A study of Homo sapiens with 4 samples.

How the data were processed

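The data are RNA-seq measurements of 4 libraries of Hs578T cells, 2 labelled as the empty group and 2 as TFCP2L1 overexpression, taken from the group named in each sample's treatment label. Per the labels' protocols, RNA was taken with Trizol and libraries were made from 1 µg of total RNA. The labels name 2 different Illumina sequencers, so the instrument is left open. The deposited table calls the control group FLAG where the labels call it empty, and its columns were matched to samples by their titles.

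The authors deposited estimated counts per gene with up to 2 decimals, not normalized, per the file headers and the values. Of the values above 0, 61.9% to 65.0% per library were whole numbers exactly as deposited. The authors deposited TPM per library next to them, per the file headers, and sums ranged from 995446 to 998049. The authors' deposited fold change (a ratio) and log2 fold change, overexpression over control, and the deposited p-value and adjusted p-value come from DESeq2, per the name of the deposited workbook. The submitters' processing notes list Bowtie 0.12.2 and build mm9, a mouse build that does not go with the human Ensembl gene IDs of the table. The aligner, counter, strand setting and annotation of the deposited counts are therefore treated as not given in the sources used here.

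The table held 60664 genes, 40609 with a symbol, and 30415 had no count in any library. GENCODE release 29 (GRCh38) was used for gene type, position, GC content and length by gene ID, and 58396 IDs matched. That release need not be the authors' annotation. Of 1021 list entries 1013 matched a gene, and the 8 others were left out. Some genes were entered under both an older and a current name, but a histone gene only under the older.

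Library depth was 23304022 and 18960674 estimated counts in the empty group and 23755664 and 26355502 in the overexpression group. The 10 most abundant genes took 5.78% to 5.91% of the counts, and mitochondrially encoded genes 3.68% and 3.60% in empty and 4.00% and 4.01% in overexpressing libraries. Libraries of a group were counted as replicates because the labels list them as separate samples. They differed by more than sampling noise (chi-square per degree of freedom 3.23 for the empty pair and 5.84 for the overexpression pair, against 65.9 for an empty and an overexpressing library), which repeated preparation of 1 RNA would also give. The common biological coefficient of variation was 0.059.

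Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust = TRUE, glmQLFTest), with TMM factors of 0.995 to 1.005, filterByExpr with its minimum count of 10, and a Benjamini-Hochberg adjusted p under 0.05 without a fold minimum. This left 16544 genes. Standard errors are the size of the log2 fold change divided by the square root of F. CPM use the TMM-scaled library sizes. Count ratios have exact 95% intervals, which cover counting error only. With 2 libraries against 2 an exact permutation test has 3 splits and cannot give a p below 0.33, so none is reported.

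The 34 gene lists, the designs and the rule for named genes were fixed before the data were examined. The lists described cover ferroptosis suppressors and drivers, NRF2 and glutathione, iron, PI3K/AKT components, their upstream receptors and ligands, FOXO targets, S phase, G2 and mitosis, mesenchymal, matrix, epithelial, basal, grainyhead, pluripotency, collecting duct, interferon, antigen presentation, NF-kB, TGF-beta, stress responses, hypoxia, sterols, oxidative phosphorylation, mitochondrial, ribosomal, histone, immediate early, heat shock, immune, endothelial, packaging-line and metastasis genes. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on voom values at a preset correlation of 0.01, with TFCP2L1 left out, and beside it with an estimated correlation and with fry. Terms of 15 to 300 tested genes were tested likewise against all tested genes carrying that annotation, 10770 for gene ontology and 5359 for KEGG.

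Named genes are TFCP2L1 and GPX4; the 12 largest rises and 12 largest falls among called genes of at least 5 CPM in the higher group, with both libraries of a group above both of the other and a gene symbol that is no clone, LINC, LOC or pseudogene name; and up to 4 called members per list, smallest p first. Some genes that this rule chose, and 1 list, are not reported here.

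Alternatives were 3 other scalings, scaling without TFCP2L1 and the 10 most abundant genes, no filter, a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, an adjusted p threshold of 0.01, a log2 fold minimum of 1 and leaving out each library. The scripts were tested on simulated data of this comparison over 16544 genes, drawn from the real means and depths. Of 50 genes changed at each size, 24% were recovered at 1.25-fold, 58% at 1.5-fold, 76% at 2-fold and 82% at 4-fold, and 11 of 16344 unchanged genes were called. Only 200 genes were changed in the simulation, against 47.5% called in the data. Its adjusted threshold was therefore stricter, and these rates do not carry over to the data. Of 34 random lists 0 were called, and a list of 30 genes raised 1.5-fold had a camera adjusted p of 1.32e-71 and a p of 0.00264 with an estimated correlation. Genes were drawn independently of each other. The random lists therefore do not test the preset correlation for lists of correlated genes, such as oxidative phosphorylation with an estimate of 0.556.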

Results

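RNA was sequenced from Hs578T, an established human breast cancer line of the triple-negative, mesenchymal kind, in 4 libraries. There were 2 libraries of cells labelled as the empty group and 2 of cells overexpressing TFCP2L1, a transcription factor of the grainyhead/CP2 family that is known from naive pluripotent cells and from kidney collecting duct. The libraries held 23304022 and 18960674 estimated counts in the empty group and 23755664 and 26355502 with TFCP2L1. Between 23921 and 25001 genes had a count in a library. The series title names GPX4, ferroptosis, proliferation, metastasis and the PI3K/AKT pathway, and the comparison asks which transcripts differed between the overexpressing and the empty cells. All fold changes are given as overexpression over empty, and means are CPM, read counts scaled to library size, ± SD over the 2 libraries of a group. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. No culture, library or sequencing batch is labelled, so a batch that coincides with the group and the group itself cannot be told apart.

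TFCP2L1 itself (ENSG00000115112; GRCh38, chromosome 2, 121216587 to 121285207, minus strand, protein-coding) had 12 and 19 counts in the empty libraries and 4623 and 5069 in the overexpressing ones. In the deposited TPM, which also scale by transcript length, these were 0.08 and 0.15 against 43.2 and 40.94. The ratio of depth-scaled counts was 263.7, with an exact 95% interval of 185.7 to 388.3 that covers counting error only, and all 4 libraries went with their labels. The table has 1 row for the gene, so transcripts of the vector and of the chromosomal gene were not separated.

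GPX4 (ENSG00000167468; GRCh38, chromosome 19, 1103926 to 1106791, plus strand, protein-coding), the enzyme that reduces lipid hydroperoxides and so restrains ferroptosis, was 1.35-fold lower with TFCP2L1. It measured 118 ± 2.07 CPM in empty cells and 86.9 ± 10.1 CPM in overexpressing cells, a log2 fold change of -0.44 (SE 0.08, edgeR quasi-likelihood adjusted p = 0.000302). Both overexpressing libraries, at 79.8 and 94.0 CPM, lay below both empty libraries, at 119.2 and 116.3 CPM. The TPM showed the same order, with 294.84 and 287.13 in empty and 199.82 and 221.78 in overexpressing cells. In the authors' deposited table the log2 fold change of GPX4 was -0.425 with an adjusted p of 7.47e-05, and its size lay under the 1.5-fold minimum behind that table's significance mark.

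Across the transcriptome, 7856 of 16544 tested genes (47.5%) differed between the groups, 3894 of them higher and 3962 lower with TFCP2L1. At an absolute log2 fold change of at least 1 the count was 2299, with 788 higher and 1511 lower. The significance mark of the authors' deposited table fell on 3006 genes, 1343 higher and 1663 lower. Of the 7856 genes called here, 5606 were also called in the authors' deposited table at an adjusted p under 0.05 in the same direction, and 0 in the opposite direction. Log2 fold changes correlated across genes at a Pearson r of 0.9994 and a Spearman rho of 0.9999 with the authors' deposited table, which rests on the same counts, and genes are not independent replicates.

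The largest rises after TFCP2L1, among genes of at least 5 CPM in the higher group, were in genes nearly silent in empty cells. CKMT1B and CKMT1A, which encode mitochondrial creatine kinase, went from 0.37 ± 0.15 to 28.7 ± 1.04 CPM and from 0.32 ± 0.15 to 20.8 ± 1.94 CPM. These are near-identical copies on chromosome 15, and how reads were divided between them is uncertain. CRYAB, a small heat shock protein, rose from 0.39 ± 0.18 to 23.3 ± 1.89 CPM, a count ratio of 57.8 (95% interval 35.9 to 99.5). SLC22A3, an organic cation transporter, rose from 0.30 ± 0.06 to 15.9 ± 2.98 CPM. HPD, an enzyme of tyrosine breakdown, reached 9.42 ± 0.22 CPM from 0.15 ± 0.09 CPM. C16orf89, RIMS4, RNF150, SLAMF8 and GCNT3 were also among them, with log2 fold changes of 5.83, 5.33, 5.02, 4.58 and 4.58.

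FABP4, a fatty acid binding protein, was among the largest falls and went from 8.42 ± 0.73 to 0.10 ± 0.03 CPM (353 counts against 5, count ratio 83.7-fold lower, 95% interval 35.5 to 259.4). ANGPTL4, an inhibitor of lipoprotein lipase, went from 23.5 ± 1.29 to 0.83 ± 0.28 CPM. SFRP1, a secreted Wnt antagonist, fell from 7.99 ± 0.91 to 0.19 ± 0.16 CPM. LAPTM5 fell from 11.7 ± 0.56 to 0.24 ± 0.10 CPM, CD180 from 17.5 ± 1.32 to 0.50 ± 0.01 CPM and RAC2 from 6.17 ± 0.17 to 0.20 ± 0.04 CPM. AVPR1A, ZPLD1 and LRRC17 had log2 fold changes of -5.89, -5.36 and -5.27. PAX8-AS1 at 83.5 ± 7.10 against 1.89 ± 0.47 CPM and CCR5AS at 7.99 ± 1.81 against 0.08 ± 0.05 CPM are antisense genes. The use of strand in counting is not given in the sources used here, so their reads cannot be told apart from those of the genes they overlap.

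**Figure D1:**
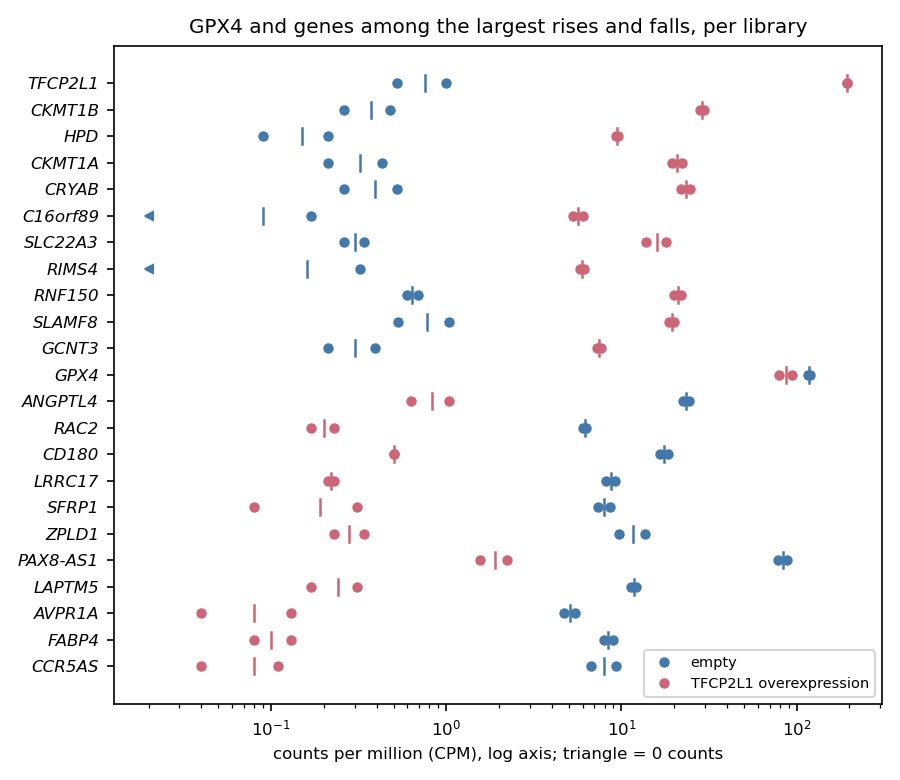
CPM on a log axis for TFCP2L1, GPX4 and genes among the largest rises and falls, with 1 point per library, a vertical tick at each group's mean and a triangle at the left for a library with 0 counts. TFCP2L1 lies at 0.76 CPM in empty and 193.7 CPM in overexpressing cells, while the 2 groups of GPX4 points lie close together at 118 and 86.9 CPM.

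**Figure D2:**
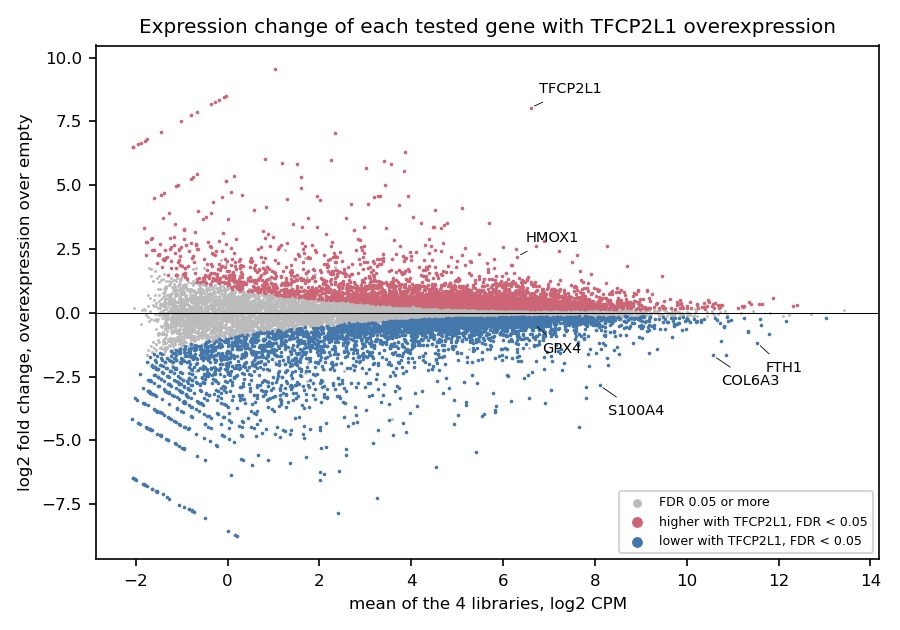
Log2 fold change of each of the 16544 tested genes against the log2 of its mean CPM over the 4 libraries, coloured by direction where the adjusted p was under 0.05. Of these, 3894 lie above 0 and 3962 below, and the slanted lines of points at the left are genes with few or 0 counts in a group, whose fitted fold changes are no bounds.

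Genes of the pathways in the title were examined as lists fixed before the data were examined. Counts of members are over all genes tested, with the count adjusted over the list alone beside them where it differed. Over all tested genes 47.5% were called, and counts of members are to be read against that share. Lists were tested with camera at a preset inter-gene correlation, adjusted over 33 lists. Of these lists 15 were called, 6 up and 9 down, and 0 with an estimated correlation, where the smallest adjusted p was 0.386 and 2 lists had an unadjusted p under 0.05. In simulated data with independent genes, a list raised 1.5-fold had a camera adjusted p of 1.32e-71, but a p of 0.00264 at that setting. The estimated setting thus raises p even without correlation between genes, so a call lost with it does not by itself count against a list. With fry, which asks whether a list's genes move on balance one way without comparing them with other genes, 23 lists were called.

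Ferroptosis genes went both ways. Of 32 tested suppressors, 13 rose and 10 fell (adjusted over the list alone, 15 and 10), and the list was not called (camera adjusted p = 0.368). PRDX6, a peroxiredoxin, rose from 143 ± 3.24 to 322 ± 7.13 CPM. SLC7A11, the cystine transporter that feeds glutathione synthesis, rose from 88.3 ± 4.88 to 215 ± 29.1 CPM. FTH1, the ferritin heavy chain that stores iron, fell from 4119 ± 329 to 1819 ± 82.7 CPM, and SCD, which makes monounsaturated fatty acids, from 1090 ± 11.98 to 556 ± 20.9 CPM. Of 37 tested drivers, 9 rose and 15 fell (adjusted over the list alone, 10 and 16; camera adjusted p = 0.227). Among them HMOX1, heme oxygenase 1, rose from 28.3 ± 3.05 to 129 ± 3.88 CPM, while DPP4 fell from 23.7 ± 0.49 to 3.03 ± 0.67 CPM. The ferroptosis pathway of the KEGG annotation in the table had 9 of 32 genes higher and 13 lower (camera adjusted p = 0.855). In the iron handling list 5 of 22 rose and 10 fell (camera adjusted p = 0.208; fry, lower, adjusted p = 0.00923), with ACO1, an iron-sensing aconitase, going from 77.5 ± 0.56 to 45.9 ± 1.51 CPM.

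Targets of NRF2, the oxidant-responsive transcription factor, and glutathione genes were higher as a list, with 14 of 25 risen and 4 fallen (adjusted over the list alone, 15 and 5; camera adjusted p = 0.0156). The call was lost with an estimated correlation (adjusted p = 0.44) and without members shared with other lists (adjusted p = 0.144). OSGIN1 rose from 6.32 ± 0.32 to 20.2 ± 1.34 CPM and TALDO1, of the pentose phosphate pathway, from 238 ± 5.32 to 402 ± 28.8 CPM.

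PI3K/AKT components went both ways. Of 42 tested members, 8 rose and 12 fell (adjusted over the list alone, 8 and 13), a share close to the 47.5% called over all tested genes. The list was not called by camera (adjusted p = 0.40) but was lower with fry (adjusted p = 0.0383). PIK3R3, a regulatory subunit, rose from 12.6 ± 0.27 to 51.2 ± 3.53 CPM, and PIK3CD, a catalytic subunit, fell from 72.2 ± 1.21 to 20.5 ± 2.65 CPM. RHEB, an activator of mTORC1, rose from 123.1 ± 0.06 to 194 ± 7.85 CPM, and the kinase SGK1 fell from 41.9 ± 2.85 to 21.7 ± 0.56 CPM. Receptors and ligands upstream of the pathway were lower as a list, with 8 of 30 risen and 16 fallen (camera adjusted p = 0.0454). That call was lost with an estimated correlation (adjusted p = 0.386), without overexpression replicate 2 (adjusted p = 0.0561), with a filter of 1 CPM in 2 libraries (adjusted p = 0.0564) and without members shared with other lists (adjusted p = 0.144). AREG, an EGF receptor ligand, fell from 22.5 ± 0.18 to 2.71 ± 0.21 CPM, VEGFC from 126 ± 13.5 to 38.4 ± 0.63 CPM and PDGFC from 64.6 ± 5.79 to 28.2 ± 0.13 CPM. The KEGG PI3K-Akt pathway had 62 of 238 genes higher and 98 lower (camera adjusted p = 0.201). FOXO targets, which AKT signalling represses, had 7 of 20 risen and 6 fallen (camera adjusted p = 0.497), with FBXO32 rising from 155 ± 11.6 to 303 ± 13.96 CPM and CITED2 falling from 59.4 ± 2.70 to 36.2 ± 3.15 CPM.

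Genes of G2 and mitosis rose together, 45 of 46 with 0 fallen and a median log2 fold change of 0.66 (camera adjusted p = 1.48e-21; adjusted p = 0.386 with an estimated correlation). KIF23, a cytokinesis motor, rose from 122.5 ± 1.04 to 255 ± 3.25 CPM, NUSAP1 from 59.7 ± 5.03 to 136 ± 3.05 CPM, and the cyclins CCNB2 and CCNA2 from 65.7 ± 2.29 to 134 ± 1.40 CPM and from 92.5 ± 4.08 to 174 ± 1.08 CPM. KIF23, NUSAP1 and CCNB2 lie on chromosome 15, whose protein-coding genes had the highest median log2 fold change of any chromosome, 0.192. With the median of neighbouring genes removed, an alternative chosen after seeing the data, the list's median was 0.682. S phase and replication genes were split, with 17 of 45 risen and 10 fallen (adjusted over the list alone, 18 and 15; camera adjusted p = 0.383). RRM2, a subunit of ribonucleotide reductase, rose from 288 ± 19.1 to 508 ± 8.59 CPM and UNG, a uracil glycosylase, fell from 103 ± 0.37 to 55.2 ± 5.27 CPM. Replication-dependent histone genes were lower, 9 of 11 fallen and 0 risen with a median of -1.61 (camera adjusted p = 0.00019; adjusted p = 0.386 with an estimated correlation). H2AC6 fell from 33.7 ± 3.30 to 8.33 ± 0.69 CPM and H1-2 from 34.2 ± 2.46 to 16.4 ± 2.35 CPM, while SLBP, which binds the stem-loop of histone mRNA, rose from 62.7 ± 0.55 to 108 ± 7.77 CPM. Histone genes are near-identical copies, so the value of each is uncertain.

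Matrix genes were lower with TFCP2L1. In the list of collagens and matrix, 28 of 39 fell and 6 rose, with a median log2 fold change of -0.51 (camera adjusted p = 1.29e-06; adjusted p = 0.386 with an estimated correlation). COL6A3 fell from 2317 ± 98.7 to 725 ± 55.0 CPM, COL1A2 from 126 ± 1.12 to 34.3 ± 0.25 CPM, the laminin gene LAMA4 from 116 ± 0.85 to 20.7 ± 0.08 CPM and PLAU, urokinase, from 508 ± 18.9 to 121 ± 7.88 CPM. Receptors and adhesion genes associated with metastasis were lower as a list, with 14 of 27 fallen and 3 risen (adjusted over the list alone, 15 and 4; camera adjusted p = 0.00119; adjusted p = 0.386 with an estimated correlation). S100A4, a calcium-binding protein tied to cell motility, fell from 482 ± 5.81 to 67.0 ± 5.08 CPM, the adhesion molecule L1CAM from 62.0 ± 3.73 to 9.45 ± 0.73 CPM and the integrin ITGA6 from 225 ± 4.44 to 84.0 ± 2.21 CPM.

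Mesenchymal genes went both ways, with 10 of 32 risen and 15 fallen (adjusted over the list alone, 11 and 15). The list was not called by camera (adjusted p = 0.243), but was lower with fry (adjusted p = 0.00991) and with camera without empty replicate 1 (adjusted p = 0.0489). LOX, a collagen cross-linking enzyme, rose from 67.4 ± 5.56 to 326 ± 12.03 CPM and ACTA2, smooth muscle actin, from 6.69 ± 0.49 to 44.9 ± 0.93 CPM, while TNC fell from 863 ± 29.97 to 290 ± 19.1 CPM. Of 15 tested epithelial genes 3 rose and 7 fell (camera adjusted p = 0.159; lower with fry, adjusted p = 0.00923, and with camera without empty replicate 2, adjusted p = 0.0448), with KRT8 falling from 165 ± 1.09 to 32.8 ± 2.84 CPM and CLDN4 rising from 35.1 ± 0.82 to 73.5 ± 5.98 CPM. Of 10 basal genes 4 rose and 4 fell (adjusted over the list alone, 4 and 5; camera adjusted p = 0.47), and their median of -0.46 and mean of 0.44 differed in sign. The mean was -0.006 without KRT5, left out after its value was seen. The median was -0.87 with a filter of 1 CPM in 2 libraries and -0.305 without overexpression replicate 1, and the list was lower with fry (adjusted p = 0.0115). KRT5, a basal keratin, rose from 0.34 ± 0.18 to 7.72 ± 1.66 CPM and LAMB3 fell from 499 ± 17.8 to 182 ± 11.5 CPM. TGF-beta responsive genes had 7 of 24 risen and 13 fallen (camera adjusted p = 0.063), with BMP2 falling from 10.3 ± 0.64 to 1.32 ± 0.03 CPM. That list was lower with fry (adjusted p = 0.00436) and with camera without empty replicate 1, empty replicate 2 or overexpression replicate 1 (adjusted p = 0.0227, 0.0311 and 0.0434), and with the median of neighbouring genes removed (adjusted p = 0.0453). Immediate early genes had 5 of 23 risen and 10 fallen (adjusted over the list alone, 5 and 11; camera adjusted p = 0.0693), with JUNB falling from 113 ± 1.53 to 32.9 ± 1.03 CPM. They were lower with fry (adjusted p = 0.00519) and with camera without empty replicate 1 or overexpression replicate 1 (adjusted p = 0.0337 and 0.0434), and with the median of neighbouring genes removed (adjusted p = 0.0468).

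**Figure D3:**
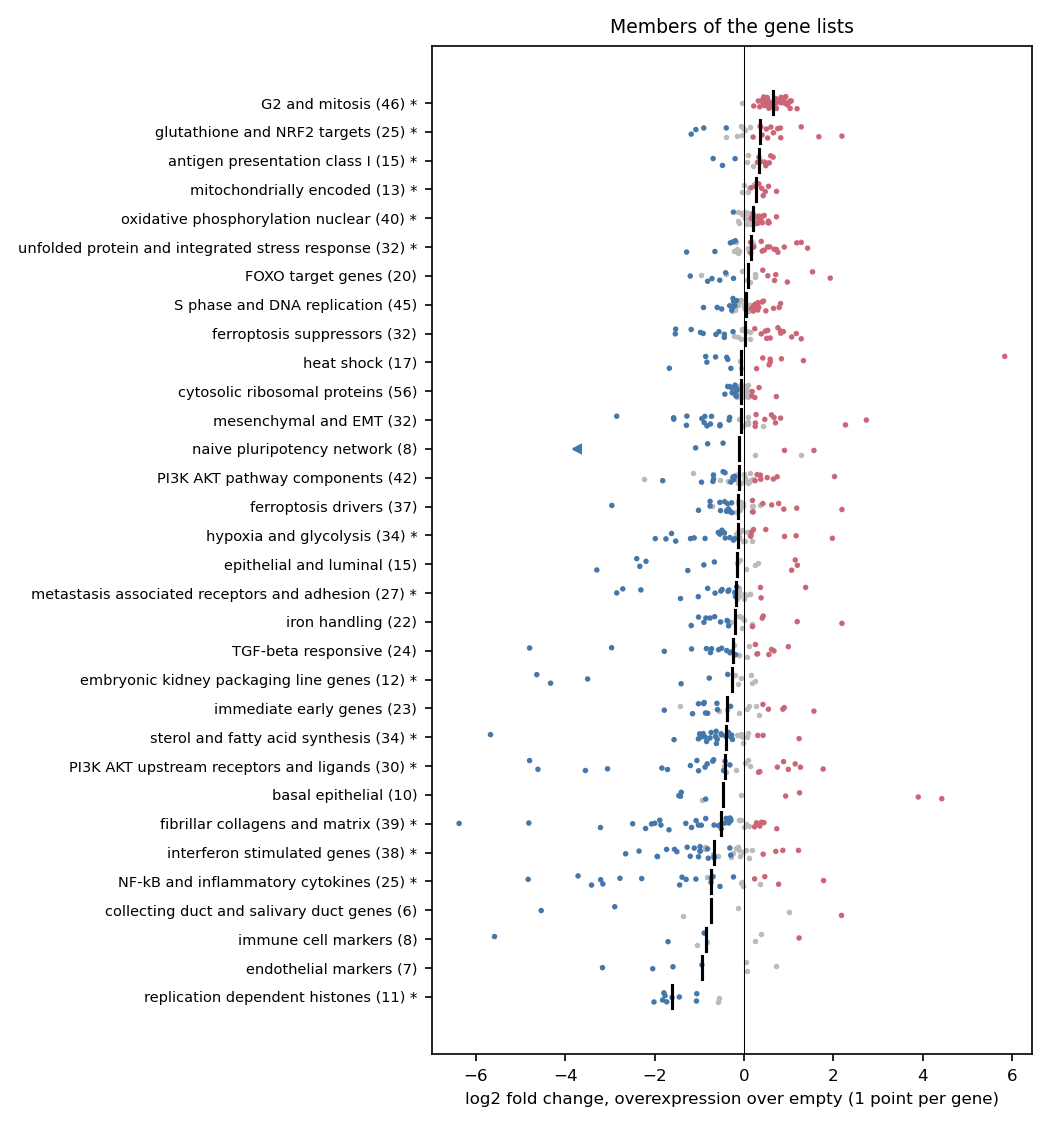
Log2 fold change, overexpression over empty, of the tested members of 32 of the lists tested, with 1 point per gene, red or blue where the adjusted p was under 0.05, a black bar at the list's median and an asterisk where the list was called by camera with the preset correlation; the triangle is ESRRB, drawn at its bound. Lists run from G2 and mitosis at a median of 0.66 to replication-dependent histones at -1.61, and the number of tested members stands in brackets.

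Inflammatory and interferon genes were lower. In the NF-kB and cytokine list 16 of 25 fell and 4 rose (adjusted over the list alone, 17 and 4; camera adjusted p = 0.000433; adjusted p = 0.386 with an estimated correlation). CXCL8, the neutrophil chemoattractant, fell from 46.2 ± 5.50 to 5.2 ± 1.48 CPM, ICAM1 from 18.5 ± 1.61 to 2.70 ± 0.10 CPM, PTX3 from 55.7 ± 10.6 to 5.23 ± 0.75 CPM and IL11 from 98.8 ± 10.6 to 36.5 ± 1.02 CPM. Of 38 interferon-stimulated genes 20 fell and 4 rose (adjusted over the list alone, 21 and 4; camera adjusted p = 0.0012; adjusted p = 0.386 with an estimated correlation). IFITM3 fell from 181 ± 4.02 to 54.7 ± 5.23 CPM and BST2 from 59.2 ± 3.48 to 15.4 ± 1.77 CPM. Genes of class I antigen presentation, many of them inducible by interferon, were higher, with 8 of 15 risen and 3 fallen (camera adjusted p = 0.0267). That call was lost with an estimated correlation (adjusted p = 0.45) and without empty replicate 1 (adjusted p = 0.0512). It was also lost (adjusted p = 0.0948) when the median of neighbouring genes on the chromosome was removed, an alternative chosen after seeing the data, which took the list's median from 0.335 to 0.184. B2M rose from 765 ± 21.3 to 1072 ± 62.4 CPM and HLA-B from 201 ± 2.37 to 316 ± 22.1 CPM.

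Sterol and fatty acid synthesis genes were lower, 23 of 34 fallen and 3 risen with a median of -0.39 (camera adjusted p = 1.46e-06; adjusted p = 0.386 with an estimated correlation). HMGCS1 of the mevalonate pathway fell from 225 ± 5.61 to 76.1 ± 3.07 CPM, whereas SREBF1, which encodes a regulator of lipid synthesis, rose from 50.8 ± 2.12 to 119 ± 7.06 CPM. Nuclear genes of oxidative phosphorylation were higher, 22 of 40 risen and 1 fallen (adjusted over the list alone, 23 and 1; camera adjusted p = 0.00019; adjusted p = 0.582 with an estimated correlation), and the call was also lost with fry (adjusted p = 0.0829). ATP5MC1 rose from 50.3 ± 2.34 to 83.2 ± 4.70 CPM. Of 13 mitochondrially encoded genes 8 rose and 0 fell (camera adjusted p = 0.00115; adjusted p = 0.386 with an estimated correlation), with MT-ND2 going from 2229 ± 18.0 to 3009 ± 49.1 CPM. Hypoxia and glycolysis genes were lower, 15 of 34 fallen and 7 risen (camera adjusted p = 0.0454). The call was lost with an estimated correlation (adjusted p = 0.629), with fry (adjusted p = 0.0659), without empty replicate 2 (adjusted p = 0.158) and without shared members (adjusted p = 0.148). CA9 fell from 69.3 ± 1.88 to 24.0 ± 2.41 CPM and P4HA2 rose from 186 ± 1.11 to 418 ± 5.14 CPM. Genes of the unfolded protein and integrated stress responses were higher, 16 of 32 risen and 5 fallen (adjusted over the list alone, 17 and 5; camera adjusted p = 0.0388), and the call was lost with an estimated correlation (adjusted p = 0.386), with a filter of 1 CPM in 2 libraries (adjusted p = 0.0564) and without shared members (adjusted p = 0.226). STC2 rose from 383 ± 40.5 to 1029 ± 16.2 CPM. Heat shock genes had 8 of 17 risen and 7 fallen (camera adjusted p = 0.592), and HSPA8 fell from 4552 ± 120.0 to 2564 ± 3.16 CPM. Their median of -0.055 ranged from -0.082 with upper quartile scaling to -0.022 without a low-count filter, and their mean of 0.31 was -0.033 without CRYAB (log2 fold change 5.84), left out after its value was seen. Of 56 cytosolic ribosomal protein genes 5 rose and 12 fell (adjusted over the list alone, 5 and 10; camera adjusted p = 0.227), and the list was called lower without overexpression replicate 2 (adjusted p = 7.62e-05).

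Lists of genes tied to TFCP2L1 in other cells were not called by camera. Of 8 tested genes of the naive pluripotency network, 2 rose and 4 fell (adjusted over the list alone, 3 and 4; camera adjusted p = 0.592), with KLF4 rising from 11.8 ± 2.17 to 34.9 ± 0.09 CPM and KLF5 falling from 22.9 ± 1.47 to 10.8 ± 0.78 CPM. ESRRB had 34 counts over the empty libraries and 0 over the overexpressing ones, at least 13.4-fold lower against a floor of 3 counts over the group. The list's median was -0.10. Placing ESRRB at that bound could not move the median, since ESRRB lies below it either way. That median changed sign when 1 library was left out, to 0.029 without empty replicate 1 and 0.001 without overexpression replicate 2, and was -0.20 without overexpression replicate 1. Of 6 collecting duct and salivary duct genes 1 rose and 2 fell (camera adjusted p = 0.401), and the list was lower with fry (adjusted p = 0.0355). SCNN1A, a sodium channel subunit, rose from 0.59 ± 0.08 to 2.71 ± 0.38 CPM while AQP3 fell from 22.7 ± 1.43 to 3.04 ± 1.04 CPM and ATP6V0D2, a V-ATPase subunit of acid-secreting cells, from 43 counts to 2. The grainyhead list had 3 tested members besides TFCP2L1 and was not tested as a list, with 1 risen and 0 fallen (adjusted over the list alone, 2 and 1).

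Markers of other cell types were measured alongside. Immune markers had 1 of 8 risen and 3 fallen (camera adjusted p = 0.401), with CD68, also a lysosomal protein, rising from 37.1 ± 1.42 to 87.3 ± 1.38 CPM. LAPTM5, given above among the largest falls, ITGAM and CSF1R fell, with log2 fold changes of -5.58, -1.70 and -0.888. Endothelial markers had 0 of 7 risen and 4 fallen (adjusted over the list alone, 1 and 4; camera adjusted p = 0.131), with PECAM1 falling from 29.7 ± 6.23 to 9.93 ± 0.01 CPM and VWF, TIE1 and ESAM also fallen. The endothelial list was lower with fry (adjusted p = 0.00863) and with camera without empty replicate 1 or 2 (adjusted p = 0.0489 and 0.0342). Genes known from embryonic kidney packaging lines were lower, 6 of 12 fallen and 0 risen (camera adjusted p = 0.0177; adjusted p = 0.386 with an estimated correlation). Among them NEFL, a neurofilament gene, fell from 27.0 ± 0.37 to 1.34 ± 0.06 CPM and IGF2BP3, an RNA-binding protein, from 73.2 ± 0.62 to 27.7 ± 2.44 CPM. GAGE1, a cancer-testis gene with near-identical copies and so uncertain, went from 66.9 ± 4.06 to 5.91 ± 0.59 CPM.

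Annotation terms carried by the deposited table were tested without choosing them in advance. Among 772 gene ontology terms 8 were higher and 4 lower, led by chromosome segregation (33 of 56 genes risen, 3 fallen, camera adjusted p = 0.000711) and extracellular matrix organization (24 of 130 risen, 73 fallen, camera adjusted p = 0.000711). Cholesterol biosynthesis had 18 of 31 genes fallen and 3 risen (camera adjusted p = 0.0209). Among 298 KEGG pathways 6 were higher and 9 lower, led by oxidative phosphorylation (57 of 120 risen, 5 fallen, camera adjusted p = 0.000797) and hematopoietic cell lineage (8 of 44 risen, 28 fallen, camera adjusted p = 0.00105). The KEGG pathway of collecting duct acid secretion had 12 of 20 genes risen and 1 fallen (camera adjusted p = 0.0496); most of its tested genes encode V-ATPase subunits, and the 1 fallen was ATP6V0D2. With an estimated correlation camera called 0 terms, where all gene ontology terms named had an adjusted p of 0.987 and all KEGG pathways named 0.916, and 4 gene ontology terms and 3 KEGG pathways had an unadjusted p under 0.05. As for the lists, that setting raises p even without correlation, so it does not by itself count against a term.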

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

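The count of called genes stayed within 1.5 times its value under the other scalings, filters, tools and the 0.01 threshold, from 5684 with DESeq2 to 8184 without a filter, and between 5953 and 7858 when 1 library was left out, which assumes that the lone library varies like the other group. A log2 fold minimum of 1 left 2299 genes, 788 higher and 1511 lower, and it removes GPX4, whose log2 fold change of -0.438 is smaller, by its construction. GPX4 stayed lower and called in each other setting, between -0.558 and -0.316 when a library was left out, and TFCP2L1 stayed higher and called in each setting, between 7.59 and 8.54 when a library was left out. Camera with an estimated correlation called 0 lists and 0 terms, against 15 and 27 with the preset correlation of 0.01. The sterol, upstream PI3K/AKT and stress response lists lost their calls although their estimates of -0.024, -0.02 and 0.001 lay under the preset. For the sterol list the unadjusted camera p went from 1.33e-07 to 0.026. A correlation above the preset therefore cannot account for these losses. The other called lists had estimates above 0.01. For the mitochondrially encoded list, with an estimate of 0.014, the unadjusted camera p went from 0.000243 to 0.0693. The simulated list of independent genes likewise went from a camera adjusted p of 1.32e-71 to a p of 0.00264. With 2 libraries per group the estimated setting thus raises p without any correlation, and its losses do not tell correlated lists from others. How much correlation added for these lists was not tested. Fry called 23 lists, among them 13 of the 15. Leaving out a library gave 15 to 18 lists. An alternative chosen after seeing the data removed the median of 51 neighbouring protein-coding genes, a list's own members left out, and gave 16 lists; class I antigen presentation lost its call. Of the genes the naming rule chose, 45 lost their call under the log2 fold minimum, and ESAM, GRHL1 and ITGAM lost it with DESeq2; with a library left out 1 to 2 genes, from these 3, lost it in 3 of the 4 fits, and none reversed. At the 0.01 threshold ESAM and ITGAM also lost their call (adjusted p = 0.014 and 0.011, edgeR). With a filter of 1 CPM in 2 libraries, 136 of 139 named genes besides TFCP2L1 and GPX4 were tested, and these kept their call. Alternatives planned for a table without counts did not apply and were not run. No paired analysis was possible because the labels number the 4 libraries in 1 series across both groups and nothing in them pairs a library of a group with one of the other; the replicate numbers used here only name libraries within a group. Depth limits the genes with few counts in a group, and the simulated data show that many changes of the smallest size simulated are missed with 2 libraries per group.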

Other observations

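Several gene groups outside the fixed lists were looked at after their values had been seen, and their members were picked by name at that point, so they carry no test as groups. Subunits of the V-ATPase, the proton pump of lysosomes, had 13 of 22 tested genes risen with a median log2 fold change of 0.38, and the 1 fallen was ATP6V0D2 (log2 fold change -4.54). Retinoid binding and metabolism genes went both ways, 9 of 18 risen and 5 fallen. CRABP2, a retinoic acid binding protein, rose from 3.78 ± 0.19 to 65.3 ± 6.21 CPM (SD over 2 libraries) and DHRS3, a retinal reductase, from 0.83 ± 0.05 to 15.8 ± 0.42 CPM, while CYP26B1, which breaks down retinoic acid, fell from 33.6 ± 5.86 to 4.02 ± 0.52 CPM. Of 26 small keratin and S100 genes 4 rose and 16 fell. Cancer-testis families, many of them near-identical copies and so uncertain, had 6 of 52 risen and 21 fallen. Of 19 natriuretic receptor and cyclic nucleotide phosphodiesterase genes 5 rose and 6 fell, with PDE5A, a cGMP phosphodiesterase, rising from 0.65 ± 0.13 to 12.3 ± 0.93 CPM and NPR1, PDE1B and PDE6B falling (log2 fold changes -3.94, -3.32 and -2.77).

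Of the tests below, those of the shift along chromosomes, of S phase genes and of both explanations for the histone genes were chosen after the result was seen, and the chromosome explanation was divided into whole cause and contribution at that point. Positions are those of GRCh38.

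Of the tested genes 47.5% were called, and the changes shared shifts along chromosomes. Median log2 fold changes of protein-coding genes ran from 0.19 on chromosome 15 (68.2% of genes above 0) to -0.20 on chromosome 11 (31.0% above 0). The log2 fold changes of these genes were then capped at an absolute value of 2. Of the variance of the capped values chromosomes held 1.81%, against a median of 0.49% when 10 Mb blocks were permuted (permutation p = 1e-04, the smallest that 10000 permutations can give). Chromosome-scale dosage differences between the 2 cell populations may contribute, as a hypothesis, though co-regulation over more than 10 Mb would do the same. As the whole cause such differences are argued against by 6671 calls kept in the same direction after the local chromosome median was removed. The lowest of 4 other scalings gave 7827 calls. These scalings differed little from the main one, with medians of all genes between -0.029 and -0.002. They could hardly have changed the count, so they do not decide on scaling. The labels give 0 batch labels that differ within a group, so a culture, library or sequencing batch and the effect of TFCP2L1 cannot be told apart. TFCP2L1 itself stays an open, untested explanation.

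The rise of G2 and mitosis genes stands beside a title that names inhibited proliferation. Its median of 0.656 was 0.639 after a trend on GC content and length was removed, which argues against that trend as the cause. With upper quartile scaling, the lowest of 4 others, it was 0.629, while the median of all genes went from -0.002 to -0.029. A scaling shifts every gene alike. This comparison could therefore not set the list apart from other genes, and it does not decide on scaling. A larger share of cycling cells of every phase is argued against by the S phase list, whose median was 0.038 where at least 0.328 was needed. Its bootstrap 95% interval of -0.094 to 0.208 resampled genes, so it covers the spread between genes and not between libraries. The bound assumes that S phase genes would respond at a size near that of mitotic genes, which was not tested. The S phase median moved by more than 1.5 times with the processing, from 0.011 with upper quartile scaling to 0.106 without empty replicate 2. It stayed under that bound in each setting. A larger share of cells in G2 or mitosis, or direct regulation of these genes by TFCP2L1, may lie behind it; neither was tested, and the batch stays open as above.

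Histone cluster genes fell together, 17 of 25 with 0 risen. Their summed CPM went from 249.9 and 259.3 in empty to 89.9 and 104.2 in overexpressing libraries, 2.62-fold lower, which argues against reads having moved between near-identical copies. These transcripts mostly lack a poly(A) tail, and lower recovery of such RNA could account for the fall. The 12 small nuclear, 7SL, 7SK, Y and snoRNA genes tested had a median of -0.184, above the -0.804 needed. The bootstrap 95% interval, over genes and not libraries, was -0.743 to 0.379. With 4 of them at 5 CPM or more this was taken to decide nothing, by a minimum of 5 such genes that was set after the value was seen and without which it would have counted against the explanation. Less histone transcription or another effect of TFCP2L1 was not tested.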
